A study of Mus musculus with 10 samples.

How the data were processed

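Total RNA from the livers of 10 female targeted-replacement mice, 5 with human APOE3 and 5 with human APOE4, was labelled with biotin from 2 ug of RNA, with 1 extract per animal per the labels, and measured on one-colour arrays. The deposited values are on the log2 scale and had been made by the authors with GCRMA 2.12.1 in R 2.7.1, per the submitters' processing notes; GCRMA corrects background by probe GC content, normalizes between arrays and gives 1 value per probe set. No scanner files were used here, and any probe filter and the genome build of the array's design are not given in the sources used here. GCRMA puts transcripts that are not detected near a low floor with little spread, so differences between values under about 4 have no sure scale. A fold against a group with most or all arrays under 4 is given as a lower bound with those values set to 4. Such a bound is of the mean fold and makes no allowance for the spread between animals.

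Groups and replicate numbers were taken from the sample titles. The value table had 0 columns that belong to no sample of this series. The platform annotation gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211; no gene was named from a probe set with several symbols, and 0 symbols changed when updated through the gene ID. Of the tested probe sets 13351 had 1 symbol, covering 8535 genes, 458 had several and 923 none. Gene order and chromosomes came from RefSeq genes of GRCm38.p6 and serve only to say which genes neighbour each other.

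The 64 control probe sets were left out, and probe sets with a mean log2 value of at least 4 over all 10 arrays, whatever the genotype, were tested. APOE4 was compared with APOE3 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 14732 probe sets and a threshold of 0.05. A nominal threshold of an unadjusted p under 0.05 and a fold of at least 1.5 was kept beside it. Gene lists were tested on 1 probe set per gene, the one with the highest mean over all arrays, with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 25 lists with at least 5 measured members. Fry tests whether the members move, on balance, in one direction and does not compare them with other genes. Array quality was compared between genotypes by exact permutation tests, two-sided, over all splits of the 10 arrays. No batch, scan date or slide was given in the labels, so none was tested. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

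The design, the 31 lists, the alternative settings and the rule for naming genes were fixed before the data were examined. The rule named Apoe; up to 15 genes in each direction with the largest differences among those that passed, filled to 10 with the smallest p where fewer passed; members of each list that passed, or otherwise up to 3 with the smallest p; and Mt1, Mt2, Nqo1, Gclc, Gclm, Hmox1 and Cyp7a1 whatever their values. Some other genes the rule names are not reported here. Of the list members, 582 of 660 were on the array by name and 461 were tested; a gene that no probe set names was not analysed here. List members are described by the probe set with the highest mean, and genes past the threshold by the probe set with the smallest p.

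The procedure was tested on simulated data of the same size, 14732 probe sets in 5 against 5 arrays, with 50 changed probe sets for each size of difference. It recovered 40% of those changed by 0.5 log2, 74% at 1, 98% at 2 and 100% at 4, with 12 false calls among 169. The real comparison called 12 probe sets. With fewer calls the adjusted threshold demands a smaller unadjusted p, so these shares overstate the recovery to be had in the real data. A list shifted by 0.5 log2 was recovered and 0 other lists were called. The simulated probe sets were drawn independently of each other. The simulation therefore cannot show how often lists are called falsely where genes vary together, as on the real arrays.

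The alternatives tried were no filter and a filter at a mean of 6, eBayes with trend and robust settings, array weights, renewed quantile normalization, centring of each array on its median, values under 4 set to 4, 1 probe set per gene, all probe sets of list members, both other list tests, the replicate number as a block, and leaving out each animal in turn. The first principal component as a covariate was added after seeing the data. The number of arrays limits the precision: the median SE of a log2 difference was 0.142, and the SD within a genotype was under 0.463 for 90% of probe sets.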

Results

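Liver RNA from 10 female mice was profiled with 1 array per animal. In 5 mice the endogenous Apoe gene had been replaced by human APOE3, and in the other 5 by human APOE4, which are isoforms of apolipoprotein E, a protein of circulating lipoproteins. The mice were 3 months old, on a C57BL/6 background, and had eaten a diet with 2 g/kg of added cholesterol in which milk fat gave 41% of the energy. The labels give the time on the diet as 6 weeks in the design and as 2 months in the growth protocol, so it remains open here. The arrays held 45101 probe sets, of which 14732 had a mean log2 value of at least 4 and were tested. The median of an array lay between 2.62 and 2.67 log2, and the number of arrays limits the precision: the SD within a genotype had a median of 0.231 log2 over the tested probe sets. The comparison asks how hepatic gene expression differs between APOE4 and APOE3 animals.

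Few genes passed the adjusted threshold, and the largest differences among them lay on chromosome 7. Nlrp12, a NOD-like receptor gene, was at 9.59 ± 0.77 log2 in APOE4 livers (SD, n = 5) against 1.70 ± 0.14 in APOE3 livers (SD, n = 5). All 5 APOE3 arrays were under 4, so the transcript was at least 48.3-fold higher in APOE4 with values under 4 counted as 4. Rps9, which encodes a protein of the small ribosomal subunit, rose from 8.53 ± 0.10 in APOE3 to 13.26 ± 0.09 in APOE4 (SD, n = 5 each) by 1 of its 3 tested probe sets, a 26.5-fold difference. Cox6b2, the testis form of a cytochrome c oxidase subunit, fell from 8.86 ± 0.21 to 3.12 ± 0.82 (SD, n = 5 each), at least 27.1-fold, and 4 of the 5 APOE4 arrays were under 4. Tfpt, a partner of the INO80 chromatin remodelling complex, rose from 5.26 ± 0.23 to 6.54 ± 0.36 (SD, n = 5 each), 2.44-fold. In limma, the adjusted p was 2.2e-07 for Nlrp12, 1.1e-10 for Rps9, 9.3e-06 for Cox6b2 and 0.024 for Tfpt. The remaining tested probe sets of Rps9 differed by -0.23 (SE 0.21) and 0.03 (SE 0.077). The former was near background (4.25 in APOE3, 4.02 in APOE4), while the latter was well above it and flat (11.47 and 11.49). Those of Tfpt differed by -0.07 (SE 0.13) and 0.29 (SE 0.16), so Rps9 and Tfpt rest on 1 probe set each. Nlrp12 and Cox6b2 also rest on 1, as no other probe set of theirs was tested. By the gene order of the mouse RefSeq annotation, Nlrp12, Tfpt, Rps9 and Cox6b2 lie within a run of 15 tested genes among the 582 tested on chromosome 7.

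Among genes on other chromosomes, Bid, a pro-apoptotic member of the Bcl-2 family on chromosome 6, fell from 7.98 ± 0.31 to 5.81 ± 0.43 log2 (SD, n = 5 each), 4.51-fold. Wdfy1, which encodes a WD-repeat and FYVE-domain protein on chromosome 1, fell by 3 probe sets. The log2 difference was -2.12 (SE 0.19) by one and -2.71 (SE 0.26) by another, and with all 5 APOE4 arrays under 4 the last was at least 2.97-fold lower. The zinc finger gene Zfp386 on chromosome 12 fell from 5.67 ± 0.51 to 3.67 ± 0.42 (SD, n = 5 each). As 4 of 5 APOE4 arrays were under 4, it was at least 3.13-fold lower. A second Zfp386 probe set, also with 4 of 5 APOE4 arrays under 4, was at least 1.52-fold lower and did not pass (adjusted p = 0.30). St7 on chromosome 6 rose at least 2.05-fold, with 3 of 5 APOE3 arrays under 4. These bounds are of the mean fold and make no allowance for the spread between animals. Arhgap21, a GTPase-activating protein gene on chromosome 2, rose by 1.00 log2 (SE 0.14) by 1 low probe set (4.25 in APOE3, 5.25 in APOE4). Its second tested probe set, well above background (7.96 and 8.07), was at 0.11 (SE 0.15). Bid and St7 had 1 tested probe set each. Adjusted p-values in limma were 0.0012 for Bid, at most 0.0012 for the Wdfy1 probe sets, 0.015 for Zfp386, 0.0017 for St7 and 0.028 for Arhgap21. In each of these genes the 5 animals of one genotype lay on one side of the 5 of the other. The same held for 297 tested probe sets, 2.02% against the 0.794% that chance gives on average.

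**Figure D1:**
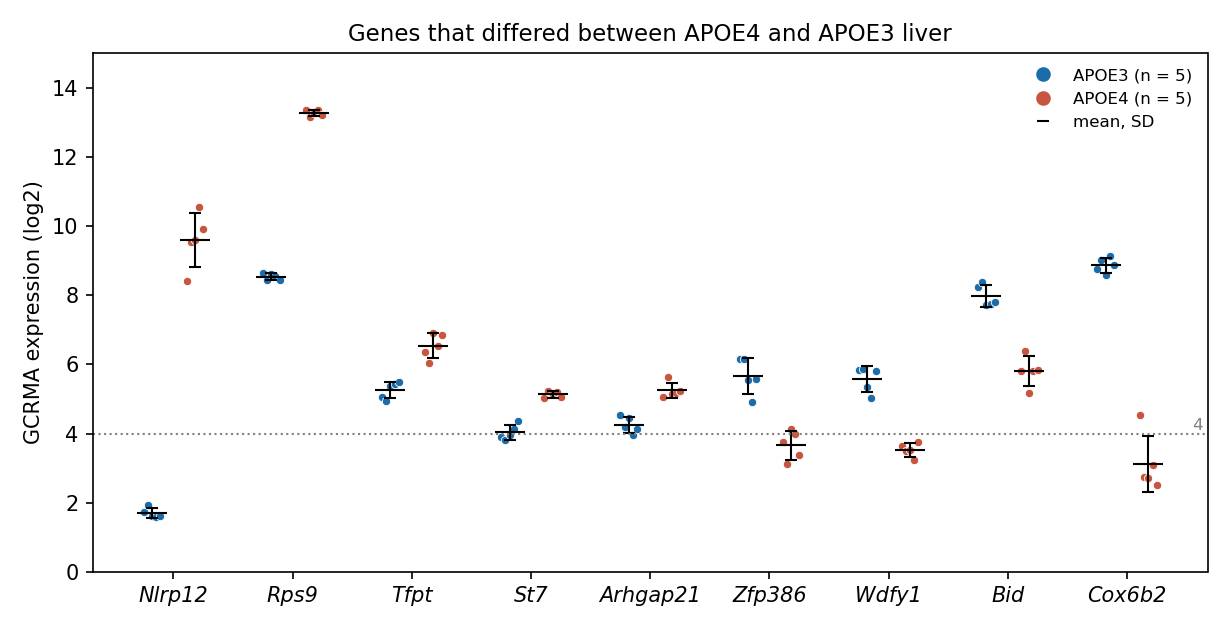
Deposited GCRMA expression on the log2 scale (vertical axis) of the 9 genes that passed the adjusted threshold (horizontal axis), 1 probe set per gene. Points are single livers of APOE3 (blue, n = 5) and APOE4 (red, n = 5) mice, bars are mean and SD, and the dotted line marks 4, under which values are near background; Nlrp12 goes from 1.70 to 9.59 and Cox6b2 from 8.86 to 3.12.

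In total, 5 probe sets were higher and 7 lower in APOE4 at the adjusted threshold, and these 12 probe sets named 5 higher and 4 lower genes. One lower probe set is unnamed here (-1.15, adjusted p = 0.033 in limma). An unadjusted p under 0.05 was reached by 1178 probe sets, where 737 would be reached on average if none differed. Of them, 133 (80 higher, 53 lower) also had a fold of at least 1.5. As many as 133 came up in 37 of 100 splits of the arrays, described below, with the real one included. The calls of Nlrp12, Rps9, St7, Cox6b2, Bid and Wdfy1 held in every fit that tested the same probe sets, but with 1 probe set per gene Rps9 is represented by another one (0.03) and was not called. The Tfpt call was lost in 8 of 10 fits that left out 1 animal (all but those without APOE3 replicate 4 or APOE4 replicate 2; adjusted p up to 0.0956), and the Arhgap21 call in 8 of 10 (all but those without APOE3 replicate 1 or 3; up to 0.108) and with renewed quantile normalization. The Zfp386 call was lost in 3, those without APOE3 replicate 5, APOE4 replicate 1 or APOE4 replicate 5 (up to 0.0706).

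The genes next in rank did not pass. On the higher side they were Dnase2a (0.68, adjusted p = 0.137 in limma), Csad, the cysteine sulfinic acid decarboxylase of taurine synthesis (1.40, 0.166), Tprkb (1.00, 0.240), Rfxap (0.56, 0.320) and Rnf121 (0.45, 0.320). On the lower side were C1galt1, the core 1 O-glycan galactosyltransferase (-1.42, 0.128), Atxn10 (-0.42, 0.320), Anxa4 (-0.59, 0.320), Syap1 (-0.61, 0.381) and Hnrnpr (-0.55, 0.381), each given as the log2 difference and the adjusted p. Hps1 was at least 1.36-fold lower, with 4 of 5 APOE4 arrays under 4 (adjusted p = 0.153). Left out in turn, 1 animal brought C1galt1 (-1.65, adjusted p = 0.0012 without APOE3 replicate 4) and Tprkb (1.15, 0.047 without APOE3 replicate 2) past the threshold.

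The labels could be checked on the replaced gene and on sex. The single probe set of mouse Apoe read 0.96 to 1.19 log2 on all 10 arrays, a background level in both genotypes, as the endogenous gene was replaced in both; it cannot tell the human isoforms apart. Xist, the RNA of the inactive X chromosome, ranged from 3.37 to 11.8 log2 over its 3 probe sets, and the Y-linked genes Eif2s3y, Kdm5d and Uty stayed at or under 2.86, 2.44 and 2.77 on all arrays labelled female. The array median was 2.66 ± 0.015 in APOE3 and 2.63 ± 0.0091 in APOE4 (exact permutation p = 0.0079), a shift of a few hundredths of a log2 unit. The 3' minus 5' difference of the Actb control probe sets, a sign of RNA integrity, was 2.68 ± 0.37 and 2.64 ± 0.20 (exact permutation p = 0.88), and that of Gapdh 0.439 ± 0.206 and 0.396 ± 0.130 (exact permutation p = 0.73).

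Of 31 gene lists fixed beforehand, 25 had at least 5 measured members, and 4 of these shifted in camera with its preset correlation. Ribosomal protein genes rose as a list: 15 of 16 measured members were positive, with a mean log2 difference of 0.137 (adjusted p = 0.00034, but 0.954 at an estimated correlation). The median of all tested probe sets was itself at 0.047, and with arrays centred the list was at 0.080 (adjusted p = 0.0065). Rpl8 was at 0.27, Rps18 at 0.23 and Rps15 at 0.19, and no member passed alone. Heat shock genes rose as a list, with 12 of 14 members positive and a mean of 0.284 (adjusted p = 0.035, but 0.954 at an estimated correlation). The chaperone genes Fkbp4 (0.47), Dnajb1 (0.61) and Chordc1 (0.43) had the smallest p in it, though not its largest differences; 0 members passed over all probe sets and 2, Fkbp4 and Dnajb1, when adjusted over the list alone. Hepatocyte markers fell as a list, with 12 of 16 members negative and a mean of -0.115 (adjusted p = 0.029, but 0.954 at an estimated correlation), among them Oat (-0.37), Hal (-0.36) and the transcription factor gene Hnf4a (-0.22). Kupffer cell and macrophage markers fell as a list, with 17 of 20 members negative and a mean of -0.235 (adjusted p = 0.029, but 0.954 at an estimated correlation). Among them were Ctss (-0.26) and the scavenger receptor gene Marco, while Cd163 was at 0.87. Marco was under 4 on 3 APOE3 and 4 APOE4 arrays. It was at 9.99 in APOE3 replicate 4, 6.62 in APOE3 replicate 2 and 4.73 in APOE4 replicate 4. So 0 of the 4 calls held at an estimated correlation, and fry called ribosomal proteins alone (adjusted p = 0.031). The adjusted p of 0.954 was common to all 25 lists. Unadjusted, camera at an estimated correlation gave p = 0.075 for ribosomal proteins and 0.16 for heat shock genes. It gave 0.24 for hepatocyte and 0.39 for Kupffer cell markers. Without 1 animal the ribosomal call held in all 10 fits; the Kupffer mean became 0.021 without APOE3 replicate 4, and that call was also lost without APOE4 replicates 2, 3 or 5 (adjusted p up to 0.862). The heat shock call was lost without APOE3 replicates 1, 3 or 5 or APOE4 replicates 1, 3 or 4 (up to 0.223), and the hepatocyte call without APOE3 replicates 3, 4 or 5 or APOE4 replicates 1, 2 or 4 (up to 0.288), its mean ranging from -0.075 to -0.181. Renewed quantile normalization and testing without a filter also ended the hepatocyte and Kupffer calls, centring ended the Kupffer call, and array weights ended the heat shock call.

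**Figure D2:**
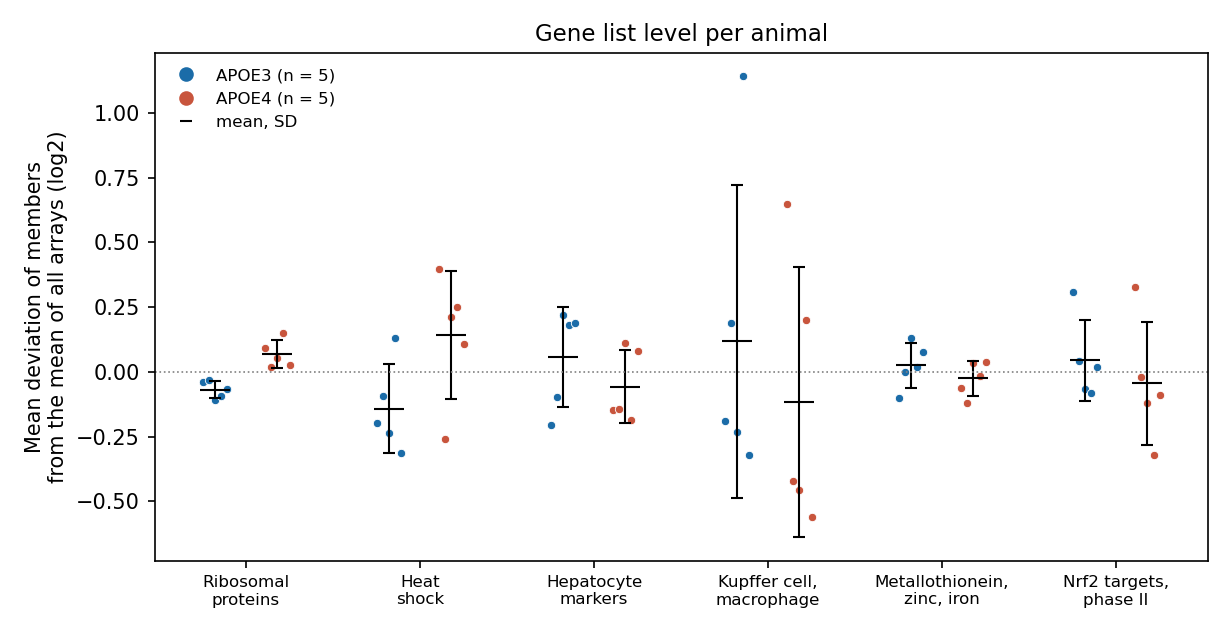
Level of 6 gene lists in each liver: the vertical axis is the mean deviation of a list's members from their mean over all arrays (log2), and the horizontal axis names the list. Points are animals of APOE3 (blue, n = 5) and APOE4 (red, n = 5), bars are mean and SD; ribosomal proteins differ by 0.137 with little spread, while the Kupffer cell list spreads widely within each genotype.

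Lists of lipid metabolism did not shift in this test, and none of their members passed. In cholesterol synthesis, 15 of 17 members were positive with a mean of 0.156 (adjusted p = 0.335 in camera). Dhcr7, the last enzyme of the pathway, was at -0.62 and the sterol carrier gene Stard4 at 0.45. The list did pass without a filter (adjusted p = 0.028) and with all probe sets of its members (0.024). In fatty acid and triglyceride synthesis, 17 of 21 members were positive with a mean of 0.220 (adjusted p = 0.232), including Dgat2 (0.27), Pklr (0.48) and Fasn (0.68). It passed without a filter (adjusted p = 0.0125) and without APOE4 replicate 4 (0.0103). PPAR alpha targets had a mean of 0.121 (adjusted p = 0.618), with the kinase gene Pdk4 at 1.39 (SE 0.63) and Hadha at 0.28. In bile acid synthesis and sterol transport, 11 members were positive and 11 negative, with a mean of -0.01 (adjusted p = 0.232). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.41 (SE 0.34), the sterol transporter gene Abcg5 at -0.38 and Slco1b2 at -0.19. It passed downward without APOE3 replicate 2 (-0.053, adjusted p = 0.031). Apolipoproteins and lipoprotein handling genes had a mean of -0.018, a median of 0.027 and a downward test (adjusted p = 0.618), with Lcat at 0.17 and Apoa2 at 0.10.

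Lists on subjects the group has studied in these mice were chosen knowing that work, so they are not independent evidence. In the metallothionein, zinc and iron list, 7 of 17 members were positive and 10 negative, with a mean of -0.050 (adjusted p = 0.257 in camera). The metallothionein genes were lower in APOE4 without passing: Mt1 was at -0.67 (SE 0.25, adjusted p = 0.58 in limma) and Mt2 at -0.78 (SE 0.33, 0.59). Nrf2 targets and phase II enzymes had 12 positive and 15 negative members and a mean of -0.089 (adjusted p = 0.241), but passed downward without APOE4 replicate 1 (-0.182, adjusted p = 0.0039). Nqo1, a quinone reductase gene, was at -0.40, Hmox1, which encodes heme oxygenase, at -1.16 (SE 0.56) and Abcc3 at -0.20. In APOE3 replicate 4 Hmox1 was at 9.15, against 5.60 to 6.64 in the other APOE3 livers and 5.12 to 6.18 in APOE4 livers. The glutathione synthesis genes Gclc and Gclm were at 0.22 and 0.17. Vitamin D metabolism had only 3 measured members and was not tested; Dhcr7 (-0.62) had the lowest p there. Adjusted over the list alone, 0 members of these 3 lists passed, as over all probe sets.

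Among lists of inflammation, stress and metabolism, the interferon response had 20 of 22 members positive and a mean of 0.186 without passing (adjusted p = 0.146 in camera). It passed without a filter (0.0125), with arrays centred (0.037) and without APOE3 replicate 2 (0.0044) or APOE4 replicates 3 (0.0011) or 5 (0.020), each an adjusted p. The antiviral gene Bst2 was at 0.24 and Dhx58 at 0.33. The unfolded protein and integrated stress response had 14 of 19 positive and a mean of 0.207 (adjusted p = 0.232), and passed without a filter (adjusted p = 0.0075) and without APOE3 replicate 4 (0.0102) or APOE4 replicate 2 (0.044). The disulfide isomerase genes Pdia4 and Pdia6 were at 0.49 and 0.58. Acute phase genes were split 11 and 11, with a mean of -0.029, a median of 0.0003 and a downward test (adjusted p = 0.605). Apcs, serum amyloid P, was at 0.47 and Orm3 at -0.69. Cytochrome P450 genes had a mean of 0.174, a median of -0.030 and a downward test (adjusted p = 0.588). Cyp3a16 was at 2.49 (SE 0.98) and Cyp3a25 at -0.21. Gluconeogenesis, glycolysis and glycogen genes had a mean of 0.087 (adjusted p = 0.890), with Irs1 at 0.61 and the glycogen synthase gene Gys2 at -0.35. The circadian clock list had a mean of -0.025 (adjusted p = 0.618), with the repressor genes Cry1 at 0.87 and Nfil3 at 0.72. Cell cycle genes had a mean of 0.122 (adjusted p = 0.739), with Rrm2 at 0.79 and Mcm7 at 0.27. Oxidative phosphorylation genes had a mean of 0.033 (adjusted p = 0.890), below 0 after centring or renewed quantile normalization. Ndufa2 was at 0.20 and Cox6c at -0.17.

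Female-biased liver genes had 8 of 11 members positive and a mean of 0.645 (adjusted p = 0.232 in camera); the 1 member that passed when adjusted over the list alone was the sulfotransferase gene Sult3a1. It was at 10.35 ± 0.92 in APOE3 and 11.85 ± 0.19 in APOE4 and did not pass over all probe sets (adjusted p = 0.396 in limma; 0.0497 without APOE3 replicate 3). The list passed without APOE3 replicate 2 (0.772, adjusted p = 0.037). Male-biased genes had a mean of 0.272, a median of 0.040 and a downward test (adjusted p = 0.769), with Hsd3b5 at 1.46 (SE 1.03) and Mup3 at -0.13. Immediate early and handling stress genes had a mean of 0.135, a median of 0.042 and a downward test (adjusted p = 0.628), with Btg2 at -0.76 and Dusp1 at 0.77. Among 21 measured neighbours of Apoe, 10 were positive and 11 negative, with a mean of -0.037 (adjusted p = 0.232). Tested for differences in either direction with limma's fry, this list had an unadjusted p = 0.043 (adjusted p = 0.533). Here 1 member, Ppp1r13l at -0.39 (SE 0.089), passed when adjusted over the list alone and did not pass over all probe sets, and Gemin7 was at 0.26.

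Of the remaining cell types, the marker lists that could be tested did not shift. Stellate cell, fibroblast and matrix genes had a mean of 0.0076, a median of -0.024 and a downward test (adjusted p = 0.618 in camera), the mean falling below 0 under both rescalings. Lrat, which esterifies retinol in stellate cells, was at 0.75 and the pericyte gene Rgs5 at -0.39. Endothelial markers had a mean of 0.045 (adjusted p = 0.890), which also fell below 0 under both rescalings, with Cdh5 at -0.34 and Lyve1 at 0.35. The other lists had too few measured members to test. Lymphocyte and NK cell markers had 2, both negative, with Ptprc at -0.41, and cholangiocyte markers 2, both negative, with Krt8 at -0.28. Adipocyte markers had 1, Car3 at 0.12, and exocrine pancreas markers 1, Cela1 at 0.17. Erythrocyte and neutrophil markers had 4, of which 3 were negative, with the neutrophil gene S100a8 at -1.01 (SE 0.37, adjusted p = 0.58 in limma).

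**Figure D3:**
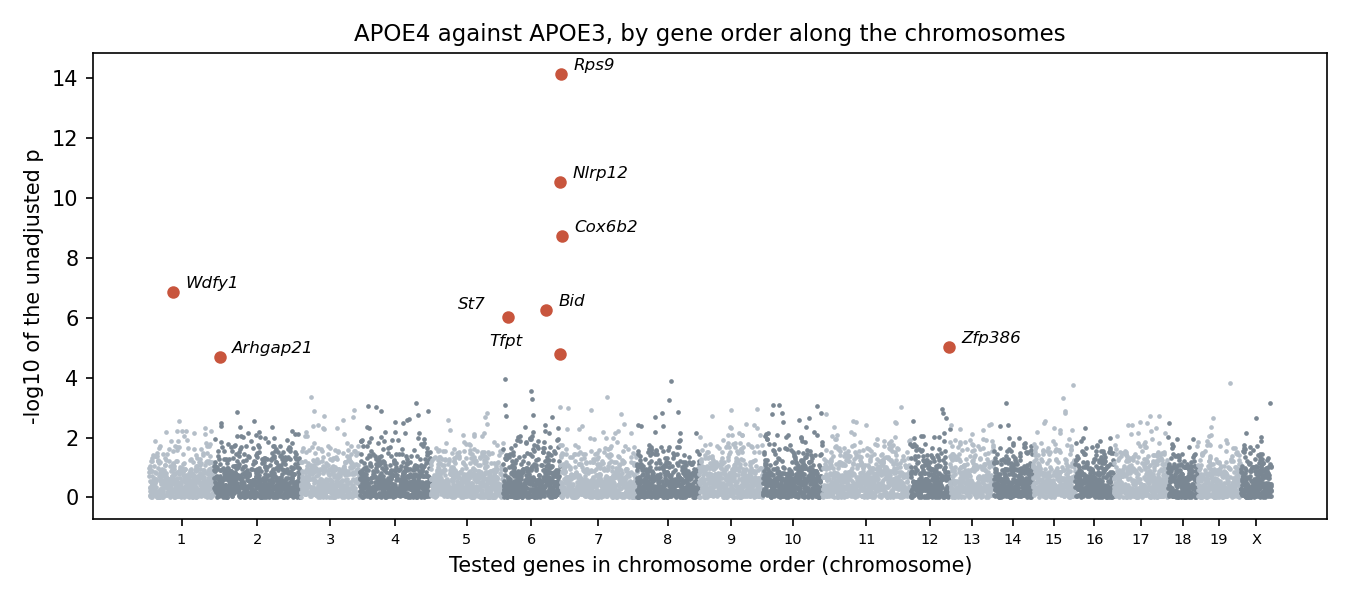
Each point is a tested gene, drawn by its probe set with the smallest p, with gene order along the chromosomes on the horizontal axis and the negative log10 of the unadjusted limma p of APOE4 against APOE3 on the vertical axis. The 9 genes past the adjusted threshold are red, and 4 of them, Nlrp12, Tfpt, Rps9 and Cox6b2, stand together on chromosome 7.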

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

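The tests of single lists against other splits of the arrays were chosen after the result was seen; those of the counts were planned. An animal far from the other 4 of its genotype was found in 9 of 226 groups of 5 values tested, and chance gives about 5%.

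Among called genes, Cox6b2 was at 4.52 in APOE4 replicate 1, with the other 4 APOE4 livers between 2.51 and 3.09. Arhgap21 was at 5.63 in APOE4 replicate 2, with the others between 5.07 and 5.23. Among genes that did not pass, C1galt1 was at 6.40 in APOE3 replicate 4 against at least 7.45 in the others of its genotype, Hnrnpr at 9.28 in APOE4 replicate 3 against at most 9.04, Stard4 at 9.13 in APOE3 replicate 2 against at most 8.18, and Hal at 10.6 in APOE3 replicate 1 against at least 11.2. Apoa2, the gene of a major HDL protein, was at 14.06 in APOE4 replicate 3 against at least 14.15, and Cox6c at 12.21 in APOE4 replicate 5 against at least 12.46. The oxidative phosphorylation list stood at 0.195 in APOE3 replicate 1, with the other 4 between -0.113 and -0.034.

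Splits of the 10 arrays into 5 and 5 that ignore genotype were fitted in the same way, 100 in all with the real one included. As many as 12 probe sets were called in 2 of 100 splits, the real one among them. Such a count was thus rare among the splits, but chance is not excluded for it. The highest other split called 91, more than the genotypes did. That split follows the first principal component of the arrays, which holds 23.6% of the variance and showed no detectable genotype difference (exact permutation p = 0.80). Its calls and the component are the same evidence of a structure of the samples other than genotype. As many as 133 probe sets past the nominal threshold were found in 37 of 100 splits, with a highest of 544, so chance is not excluded for that count.

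The list shifts were weighed against the same splits. At least 4 lists shifted in 86 of 100 splits, with a highest of 12, so the number of shifted lists does not set the genotypes apart. A camera p as small came up in 46 splits for Kupffer cell markers, in 14 for heat shock genes and in 19 for hepatocyte markers, so chance is not excluded for these lists. For ribosomal proteins, such as Rpl8 and Rps18, the real split alone reached it (1 of 100). At an estimated correlation of 0.28 between members, however, camera did not call the list (unadjusted p = 0.075, adjusted p = 0.954). If the shift is real, a genotype effect on ribosomal protein genes, or a difference between the lines or in handling that goes with genotype, may underlie it, and the design cannot separate these.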

How the results depend on the processing

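The covariate of the first principal component was chosen after seeing the data; with it 5 probe sets were higher and 7 lower, the same 12, and female-biased genes passed as a list (adjusted p = 0.036). The 12 calls were also kept with trend and robust settings, array weights, values under 4 set to 4 and no filter, which called 15, adding probe sets of Tia1 and B3galt1 and an unnamed one, all with means under 4. Renewed quantile normalization called 11, all among the 12. With a filter at 6, 1 probe set was higher, 4 were lower and 72 passed the nominal threshold, since most called probe sets have lower means. With 1 probe set per gene the counts were 3, 4 and 72, as Wdfy1 then counts once, the unnamed probe set drops out, and Rps9 and Arhgap21 are represented by other probe sets. Leaving out 1 animal gave 3 to 5 higher, 5 to 9 lower, 125 to 226 nominal (226 without APOE3 replicate 1, 204 without APOE4 replicate 2) and 2 to 7 shifted lists (7 without APOE3 replicate 2); the higher count was 3 without APOE3 replicate 5 or APOE4 replicates 1, 4 or 5. Shifted lists numbered 2 with renewed quantile normalization, 0 with an estimated correlation and 1 with fry; beyond the smaller samples and the tests' own construction the cause was not tested. Over the settings that tested the same probe sets 142 values of called genes stayed past the threshold and 22 did not, with 0 changes of sign. Where a group was near background (values under 4), only bounds of folds can be had.

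The labels number animals 1 to 5 in both genotypes, but same-numbered animals' deviations correlated at -0.079 to 0.414, and 2 of 5 APOE3 animals correlated best with their own number, so a pairing was not shown. With the replicate block 5 probe sets were higher, 6 lower, 186 nominal and 5 lists shifted; 10 of its 11 calls were among the 12, the other being a Stard4 probe set (1.06), and the Zfp386 and Arhgap21 calls were lost. Female-biased genes passed as a list with it (adjusted p = 0.045).

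Means of lists that had not shifted changed sign under some settings; the cause was not tested. Without a filter the circadian mean was 0.015 and that of Apoe neighbours 0.013. With a filter at 6 Apoe neighbours were at 0.0062 and stellate genes at -0.012. With array weights circadian genes were at 0.011, immediate early genes at -0.039 and stellate genes at -0.021. Renewed quantile normalization put oxidative phosphorylation at -0.00037, stellate genes at -0.038 and endothelial markers at -0.0021; centring put them at -0.024, -0.049 and -0.012. With all probe sets bile acid genes were at 0.025 and Apoe neighbours at 0.00059. Without 1 animal the means ranged from -0.017 to 0.195 for gluconeogenesis, -0.067 to 0.290 for immediate early genes, -0.034 to 0.00015 for apolipoproteins, -0.202 to 0.128 for the clock, -0.083 to 0.050 for bile acid genes, -0.109 to 0.016 for acute phase, -0.285 to 0.281 for the cell cycle, -0.164 to 0.156 for stellate genes, -0.075 to 0.0039 for Apoe neighbours and -0.0044 to 0.080 for endothelial markers. Of the shifted lists, Kupffer cell markers alone changed sign (-0.426 to 0.021).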

Other observations

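The tests of genes near called genes and of second probe sets, and the correlations with the first component, were chosen after the results were seen; the test of called genes by position was planned. The genes below were chosen after their values were seen.

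Several large differences did not pass, some of them with a wide spread between animals of a genotype. Cyp3a16, a female-biased P450 gene, was at 6.12 ± 2.18 in APOE3 and 8.61 ± 1.39 in APOE4 (SD, n = 5 each), and the adipokine gene Serpina12 at 7.12 ± 1.02 and 8.97 ± 0.53. Cyp26a1, which encodes a retinoic acid hydroxylase, was at a log2 difference of 1.83 (SE 0.73). Ifi27, an interferon-induced gene, was at 0.85 (SE 0.20). Their adjusted p-values in limma ran from 0.396 to 0.584.

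The largest axis of variation between these livers showed no detectable genotype difference. The first principal component of the 14049 tested probe sets that name no list gene held 23.1% of the variance, with scores of -0.83 ± 22.5 in APOE3 and 0.83 ± 15.5 in APOE4 (exact permutation p = 0.87). The scores spanned 55.7, with largest gaps of 17.2 and 13.9 between neighbours, so no clear separation into clusters was seen. Of 5 components of all tested probe sets, the third (15.5% of the variance) did differ by genotype without overlap (exact permutation p = 0.0079, adjusted p = 0.040). Its scores reached -1.23 in APOE3 and started at -0.14 in APOE4, with APOE4 replicate 1 far out at 39.6. Over the 10 arrays the first component correlated with the gluconeogenesis, glycolysis and glycogen list (Pearson r = 0.894, permutation p = 0.00071, adjusted p = 0.019; Spearman rho = 0.794, p = 0.0090; r = 0.867 without the 2 farthest animals). Hepatocyte markers gave r = 0.874 (permutation p = 0.0031, adjusted p = 0.029; rho = 0.745, p = 0.017; 0.852 without the 2 farthest), and bile acid genes r = 0.839 (permutation p = 0.0032, adjusted p = 0.029; rho = 0.842, p = 0.0039; 0.907). Metallothionein, zinc and iron genes gave r = 0.80 (permutation p = 0.0057, adjusted p = 0.038; rho = 0.806, p = 0.0075; 0.625). These 4 of 27 relations passed by r and 0 passed by rho after adjustment (smallest adjusted p = 0.081), so the ranks do not carry them past the threshold. The Actb 3' minus 5' difference gave r = -0.236 (permutation p = 0.51; rho = -0.055, p = 0.89; -0.582 without the 2 farthest).

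Nlrp12, Tfpt, Rps9 and Cox6b2 form 6 pairs of called genes within 5 Mb, where 10000 random draws of 9 tested genes gave at most 5 (permutation p = 1e-04, the smallest they can give). Within 5 Mb of called genes 11.2% of 187 other genes had an unadjusted p under 0.05 against 7.18% elsewhere (permutation p = 0.032 over circular shifts of the gene order). This rests on chromosome 7, where 7 of 24 genes (29.2%), including Myadm at 0.99, had such a p. Against genes elsewhere Fisher's exact p was 0.0012, which takes neighbouring genes as independent. Circular shifts gave that window a permutation p of 0.0014. Near the other called genes 14 of 163 had such a p (8.59%, permutation p = 0.31 over circular shifts). These windows and that on chromosome 7 were not tested against each other. A candidate explanation is that the lines, backcrossed for 8 generations per the labels, differ in segments left from the 129 strain around the targeted gene or elsewhere, so that these differences may mark the line and not the isoform. Between the run and Apoe lie 52 tested genes, and how far such a segment would reach was not determined. Isoform and line go together in this design, so an effect of APOE4 on these genes stays open and untested.

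Sequence differences under the probes may also mimic expression differences where lines differ in strain-derived segments. Probes that share sequence with another transcript may read that transcript instead. The test below does not tell these 2 causes apart. For Rps9 the other tested probe set that moved least was at 0.027 (SE 0.077) against 4.73, and for Tfpt at -0.073 (SE 0.13) against 1.28, as a cause in 1 probe set would give. Wdfy1 moved with its second probe set too (-2.12), which argues against a cause in 1 probe set. It stays open for Nlrp12, Cox6b2, Bid and St7, which have 1 tested probe set each and cannot be checked in this way. The untested Bid probe sets were also lower in APOE4, at -0.94 (SE 0.18) and -0.66 (SE 0.18), but with means under 4 in both genotypes. Such a cause also stays open for Zfp386, whose second probe set (-1.23) is near background in APOE4 (1.52-fold lower at least), and for Arhgap21 (0.109, SE 0.15, against 1.00), too near the bound set for the test. Transcript variants that only some probe sets read were not tested and stay open for Rps9, Tfpt and Arhgap21.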
